A study of Mus musculus with 12 samples.

How the data were processed

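Single-cell RNA was counted in cells of the adult mouse V-SVZ (ventricular-subventricular zone). Ai14 mice aged P27 to P30 received an intraventricular adenovirus carrying Cre and GFP 15 to 24 h before dissection, 14 mice in experiment 1 and 12 in experiment 2, and the lateral wall and the dorsal wedge were taken as separate dissections. Experiment 1 also held the lateral wall of 2 uninjected hGFAP:GFP mice of 1 year (P365 in the labels). Males and females were pooled. The series lists 12 libraries: 6 of gene expression (2 in experiment 1 and 4 in experiment 2) and 6 of MULTI-seq barcodes, which have no files of their own. Dissections were mixed before loading, so every gene expression library holds cells of each pool of its experiment, and the deposited cell table gives the pool of each cell.

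The deposited values are counts of UMIs (unique molecular identifiers) per gene and cell, which per the labels come from 10x 3' v3.1 libraries aligned with STAR to a mouse reference extended with Cre, GFP and WPRE, intronic reads included. WPRE stands in for TdTomato per the labels. STAR 2.7.11 and Seurat 5 were used, per the submitters' processing notes. The genome build, the strand of counting, the ambient RNA correction and the doublet treatment are not given in the sources used here, and no doublet caller was run. Genes carry symbols only. The deposited cell table gives the mitochondrial share as a percent of UMIs, which was recomputed from the counts with no difference. It also gives a B1 score from 0 to 1 for B cells, a score whose making the authors do not describe, so it entered no test. Cell types, the B1 and B2 names, the TdTomato names, the domain names (dorsal pallial, dorsal subpallial, ventral subpallial) and the activation states are those of the authors in the same table. B1 cells there are the union of cells named TdTomato+ and TdTomato+ NN, and what NN means is not given in the sources used here.

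The cells used number 23856, in 14 classes. Another 24261 cells in 2 lanes of the deposited table belong to no sample of the series and entered no comparison. Libraries of experiment 1 held 69938694 and 48139675 UMIs (median per cell 17406 and 13515.5), and those of experiment 2 held 28824331, 33966201, 50037986 and 47210928 (5225, 7127, 9349 and 10982.5). Library numbers were taken from the well numbers in the cell table, a match that the sources do not spell out and on which no pooled value depends. The pools held 5685 (lateral wall), 766 (wedge) and 408 (aged lateral wall) cells in experiment 1 and 10622 (lateral wall) and 6375 (wedge) in experiment 2.

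Cells are not replicates, so the counts of all cells of a class in a pool were summed, with at least 10 cells per sum. The 3 reporter sequences were left out of the sums. Comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined, and those added later are named where their values stand. Each of 6 comparisons was tested in edgeR 4.0.16 (robust quasi-likelihood F test, TMM scaling, filterByExpr) under R 4.3.3, with the experiment or pool as a block and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. The pairing in the block comes from the design: both members of a pair come from the same mice of the same experiment. The 4 sums per comparison leave 1 residual degree of freedom, and the 6 sums of B2 cells against astrocytes leave 2. In the astrocyte comparison the lateral wall and wedge pools of experiment 2 come from the same mice, so they are not independent sets of animals. The test adds variance shared across genes, with median prior degrees of freedom of 20.5 for B1 against B2 cells and 5.15 for astrocytes. For the wedge in B, B2 and A cells they were 27.1, 10.9 and 16.3. For labelled B cells the median was infinite, so for most genes there the gene's own spread did not enter. These p-values hold only spread between these pools of many mice, taken mostly over genes together, and mice within a pool cannot be told apart. Aged cells form 1 pool, so no p-value could be computed for them. Class shares and reporter shares had no planned test. All of these are given with exact Poisson or Clopper-Pearson 95% intervals, which hold counting error only.

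Named genes are the 10 largest rises and 10 largest falls past the threshold with a mean of at least 20 CPM (UMIs of a gene per 1e6 UMIs) in the higher class and the same direction in every pair, numbered and Rik symbols left out. Without a test they also needed 50 counts. Standard errors (SE) are those of the fitted log2 value. A total of 29 gene lists was fixed: ventricular stem cell, homeostatic astrocyte, ependymal and motile cilium, apical junction and primary cilium, quiescence, activation, cell cycle, neuroblast, dorsal domain, ventral domain, targets of Shh, Wnt and BMP, extracellular matrix, cholesterol synthesis, fatty acid oxidation, interferon response, MHC class I, reactive astrocyte, immediate early and dissociation, ribosomal protein, mitochondrial transcript, and markers of oligodendrocytes, oligodendrocyte precursors, microglia, endothelial and mural cells, fibroblasts, neurons, choroid plexus, T cells and erythrocytes. List tests were camera of limma 3.58.1 with a correlation of 0.01, camera with an estimated correlation, and fry. In the aged comparison each list median was ranked among 10000 random lists drawn from 20 expression bins. A fold against a group with no counts is given as a lower bound against a floor of 3 counts.

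Each fit was tested on simulated counts, drawn anew from its own fitted means and dispersions, in which 200 of the more abundant genes were changed. Genes were drawn independently, so the test holds under the assumptions of the model and leaves out correlation between genes. At 2-fold the test found 68% of changed genes for B1 against B2 cells, 62%, 70% and 83% for the wedge in B, B2 and A cells, 33% for B2 cells against astrocytes and 77% for labelled B cells. At 1.5-fold it found 19%, 29%, 30%, 73%, 0% and 40%. Wrong calls were 5 of 92, 13 of 104, 19 of 119, 18 of 174, 10 of 43 and 13 of 130.

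Alternatives were DESeq2 1.42.0 (size factors, Wald test), no filter, sums by 10x library, no block, 1 experiment alone by library, at least 30 cells per sum, cells thinned to 3000 UMIs (561 shallower cells dropped), 1 pool left out, removal of B cells with 2 or more UMIs of 5 ependymal markers, and other reporter thresholds. Added after seeing the data were fits in 1 domain, in quiescent cells, without TdTomato+ NN cells, by TdTomato name and with the reporters kept in the sums, and the aged values in B cells. With the single pair that is left when a pool is removed from 4 sums, no test is possible. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.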

Results

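The lateral wall of the ventricle and its dorsal wedge were compared cell class by cell class in 2 experiments on injected young mice, and aged cells were set beside young ones in experiment 1.

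B1 cells, the stem cells that touch the ventricle, made up 59.9% of lateral wall B cells in experiment 1 (234 of 391, 95% interval 54.8 to 64.7) and 44.1% in experiment 2 (546 of 1238, 41.3 to 46.9). Of these B1 cells 173 and 390 are TdTomato+ NN cells, whose naming is not described, so any genes used for it cannot be told from other genes that differ. In the wedge no B cell was named B1 (0 of 86 and 0 of 1055), but whether the dissection entered that name is not stated, so these counts set no limit on ventricle-touching cells there. Ependymal cells were 12.5% and 14.7% of lateral wall cells but 0.522% and 1.16% of wedge cells. B cells of the dorsal pallial domain were 59.3% and 66.9% of wedge B cells against 7.42% and 9.53% of lateral wall B cells. Ventral subpallial cells made up 51.7% and 67.8% of B1 cells and 13.4% and 29.8% of lateral wall B2 cells. Cells in the activated state were 25.6% and 11.9% of B1 cells, 56.1% and 28.2% of lateral wall B2 cells and 36.1% and 13.7% of wedge B2 cells. Neuroblasts (A cells) were 48.1% and 41.0% of the lateral wall and 44.1% and 19.9% of the wedge, while oligodendrocyte precursors were 4.15% and 4.87% against 10.2% and 11.8%. These shares have counting intervals only, and no test was planned for them.

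WPRE, the stand-in for TdTomato, was found in 92.0% (89.8 to 93.9) and 89.4% (87.8 to 90.9) of lateral wall ependymal cells, at 678 and 915 CPM. It was found in 63.9% (59.0 to 68.7) and 59.6% (56.8 to 62.4) of lateral wall B cells and in 43.02% (32.4 to 54.2) and 50.6% (47.6 to 53.7) of wedge B cells. Microglia, which arise outside the neural lineage, give the background: 28.1% (21.0 to 36.1) and 28.8% (24.9 to 32.9) in the lateral wall. Depth differs between the dissections, with medians of 15864 and 8040.5 UMIs for lateral wall B cells and 10864 and 5760 for wedge B cells. Thinned to 3000 UMIs per cell, WPRE stood at 69.2% and 76.9% in ependymal cells, 23.8% and 36.8% in lateral wall B cells, 20.9% and 31.2% in wedge B cells and 9.59% and 11.9% in microglia. B1 cells held WPRE at 189.9 and 582 CPM, lateral wall B2 cells at 47.6 and 112.0 CPM and wedge B2 cells at 54.2 and 135 CPM. Within B1 cells the TdTomato+ cells stood at 571 and 1637 CPM and the TdTomato+ NN cells at 53.2 and 103 CPM. Of wedge B cells, all named TdTomato-, 13 of 86 and 74 of 1055 had as much WPRE per UMI as the lowest TdTomato+ cell of their experiment, as did 3 of 157 and 15 of 692 TdTomato- and 6 of 173 and 3 of 390 TdTomato+ NN cells of the lateral wall. Viral GFP was in 88.2% and 91.5% of lateral wall ependymal cells, in 43 of 391 (experiment 1) and 60.3% (experiment 2) of lateral wall B cells, in 1.16% and 49.1% of wedge B cells and in 4.11% and 56.8% of microglia.

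**Figure D1:**
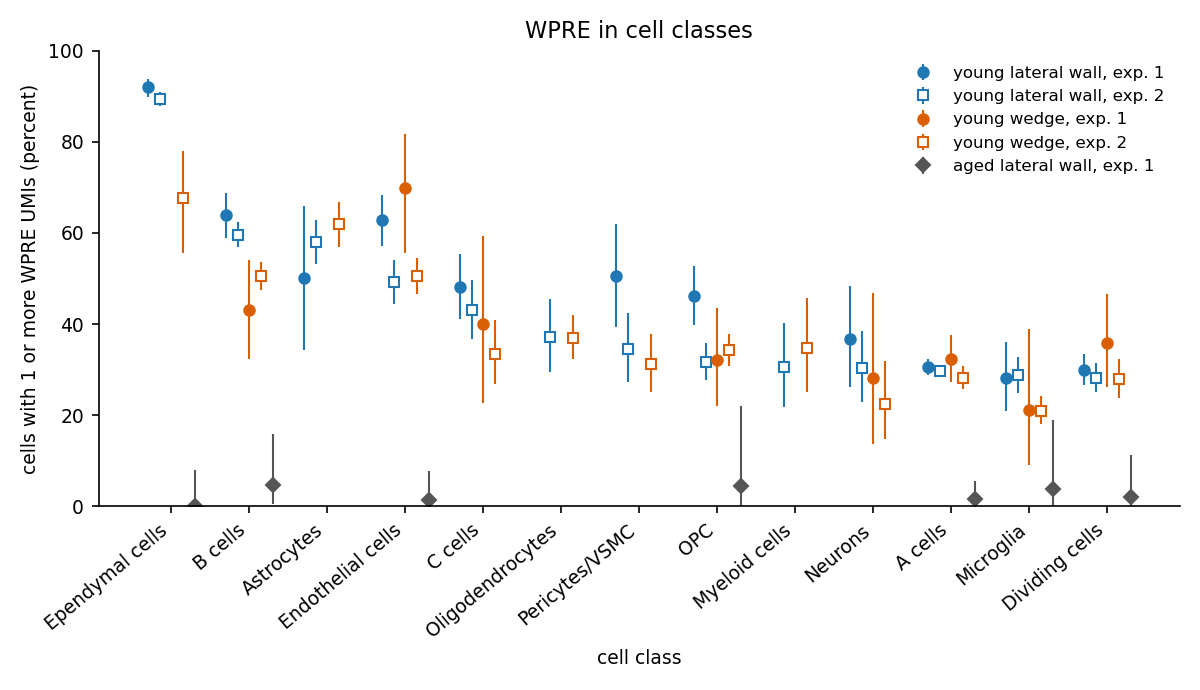
Percent of cells of each class with at least 1 WPRE UMI in the young lateral wall, the young wedge and the aged lateral wall. Bars are exact 95% counting intervals.

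Hspb1, a small heat shock chaperone, was higher in B1 cells than in lateral wall B2 cells (log2 2.99, SE 0.177, adjusted p = 3.4e-09, 124 against 15.3 CPM). So was Tgm1, a protein-crosslinking enzyme (3.01, SE 0.251, adjusted p = 1.2e-07). Complement C3 (2.91, SE 0.249), the lipopolysaccharide-binding Lbp (2.75), the chemokine Ccl7 (2.44), the protease inhibitors Timp1 (2.24) and Serpina3n (2.13, adjusted p = 2.9e-08) were higher too. So was the axonemal Cfap45 (2.10). Lower in B1 cells were Hells, a chromatin remodeller of dividing cells (-2.37, SE 0.279, adjusted p = 7.6e-06), the neuronal regulators Myt1l (-2.35) and Srrm4 (-1.95), and Adarb2 (-2.11), Synpr (-2.06) and Foxp2 (-2.03). Dlx6os1 was lower as well (-2.43, SE 0.163), but it is an antisense transcript and the strand of counting is not stated. The receptor Egfr (-1.26, SE 0.151, adjusted p = 1.1e-05, 171 against 391 CPM), of activated progenitors, was lower. So was the microtubule gene Dcx of migrating neuroblasts (-1.90). In quiescent cells alone these directions turned for Dcx (0.12), Synpr (0.45) and Dlx6os1 (0.015), and in dorsal subpallial cells for Dlx6os1 (0.45) and Adarb2 (0.37).

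Of 17 measured ependymal and motile cilium genes, 10 rose in B1 cells and 7 did not pass (13 rose when adjusted over the list alone). The list had a median of 1.25 and camera adjusted p = 5.5e-12. It had a median of 0.73 in ventral subpallial cells, 0.52 in dorsal subpallial cells and 0.49 without B cells holding ependymal marker UMIs, and edgeR called none of its 13, 7 and 5 genes there. The last setting drops cells by 5 genes of this same list and removes 72.65% and 78.02% of B1 cells. Its lower median is therefore partly built in. Foxj1, the master regulator of motile cilia, rose by 1.51 (167 against 58.1 CPM), Cfap126 by 1.88 and Pifo by 1.92. The ependymal genes Tmem212 (0.29, adjusted p = 0.78) and Ccdc153 (-0.71, adjusted p = 0.52) did not pass. Reactive astrocyte genes rose in 7 of 12 cases (9 over the list alone, median 1.23, camera adjusted p = 3.4e-20), Vim by 1.07. All 8 MHC class I genes rose (8 over the list alone, median 0.96, camera adjusted p = 1.6e-11), H2-K1 by 1.36. Likewise 11 of 17 interferon genes rose (13 over the list alone, median 0.69, camera adjusted p = 2.7e-12). B1 cells carry TdTomato names, and that label depends on the injected Cre virus. A response to virus was therefore not separated from B1 identity for any gene or list of this comparison. Cholesterol synthesis rose in 9 of 14 genes (10 over the list alone, median 0.50, camera adjusted p = 8.0e-06). Of 14 immediate early genes, which dissociation can also induce, 10 rose (14 over the list alone, median 0.82, camera adjusted p = 1.6e-17). The neuroblast list fell in 12 of 13 genes (12 over the list alone, median -1.58, camera adjusted p = 2.0e-27). The activation list fell in 10 of 14 (11, median -0.90, camera adjusted p = 5.6e-12) and the cell cycle list in 13 of 28 (15, median -1.01, camera adjusted p = 2.4e-11). Dorsal domain genes fell in 2 of 8 cases (3 over the list alone, median -0.72) and neuron markers in 2 of 4 (3, median -1.36), each with camera adjusted p = 0.0016. With an estimated correlation each of these 11 lists had adjusted p = 0.758, and by fry they ranged from 0.0492 for neuron markers to 0.505.

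Ventral domain genes split, with 2 up and 2 down of 8 (3 and 3 over the list alone): Crym (1.44) and Nkx6-2 (1.68) rose. The list's median of 0.40, mean of -0.04 and upward camera test (adjusted p = 0.0989) differ in sign. Ventricular stem cell genes split too (4 up and 2 down of 10, median 0.30, camera adjusted p = 0.0945), Vcam1 at 0.81 and Hopx at -1.16. Lists with few calls were homeostatic astrocyte (1 of 21 up, median 0.32), quiescence (2 of 16 up, median 0.27) and apical junction and primary cilium (2 of 16 up, median 0.12). So were extracellular matrix (1 up and 1 down of 16), targets of Shh, Wnt and BMP (1 up and 1 down of 10) and ribosomal protein (1 of 91 up). No fatty acid oxidation gene of 12 and no mitochondrial transcript of 13 passed. Among markers of other cells, 1 of 4 oligodendrocyte genes, 1 of 6 endothelial and mural genes and the 1 measured fibroblast gene rose. No microglial gene of 7 or oligodendrocyte precursor gene of 4 passed, and choroid plexus, T cell and erythrocyte markers were too low to measure. Median and mean differ in sign for oligodendrocyte markers (-0.04 and 0.07), and median and camera direction for endothelial and mural markers (median -0.20) and oligodendrocyte precursors (median 0.27).

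Of 13418 genes tested, edgeR called 888 higher and 566 lower in B1 cells, 313 and 240 of them by more than 2-fold. DESeq2 called 397, and edgeR without the replicate block called 0 (557 at an unadjusted p under 0.05). After removal of B cells with ependymal marker UMIs, which drops 72.65% and 78.02% of B1 cells, 159 passed. In ventral subpallial cells 217 passed and in dorsal subpallial cells 0 (1003 at an unadjusted p under 0.05, edgeR). In quiescent cells the cell cycle median was 0.08, the neuroblast median 0.07 and the activation median -0.121 (2 up and 3 down of 12). In ventral subpallial cells medians were -0.152 for activation, -0.151 for neuroblast (1 up of 11), 0.111 for immediate early (2 up of 14) and 0.166 for cholesterol synthesis genes (9 of 14 above 0).

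**Figure D2:**
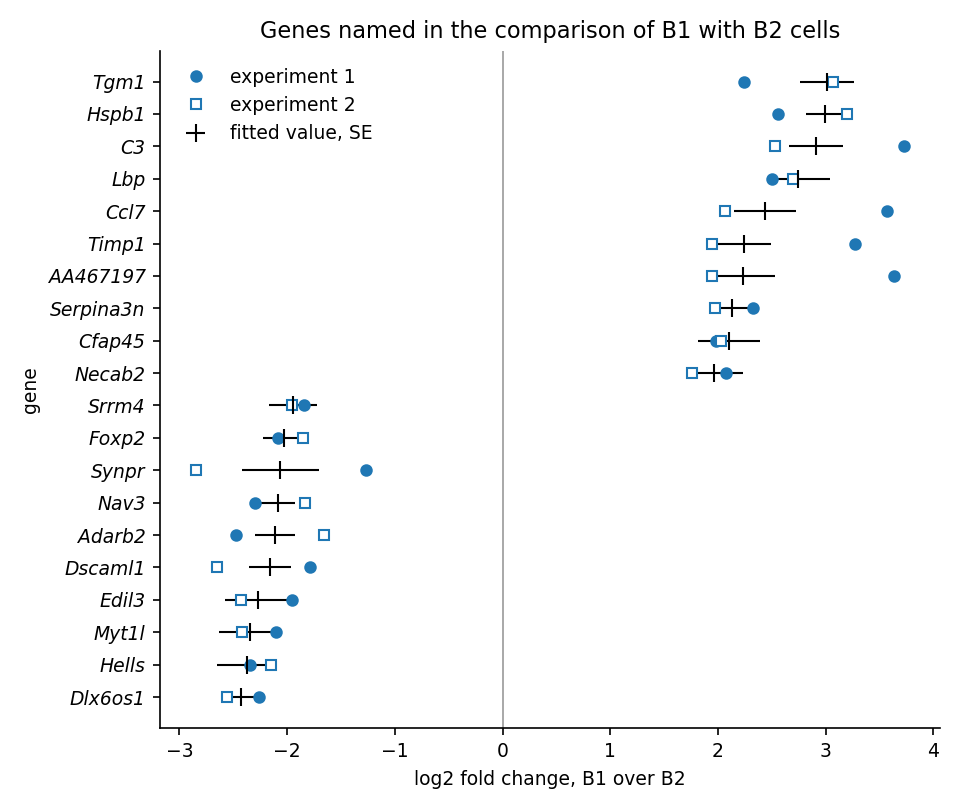
Named genes of B1 against lateral wall B2 cells, as log2 fold change in each experiment and as fitted value with its SE.

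In B cells Tfap2c was higher in the wedge than in the lateral wall (log2 4.07, SE 0.277, adjusted p = 1.0e-11, 39.1 against 2.25 CPM). So were Dmrta2 (2.89, SE 0.217), Zic2 (2.80), Nr2f1 (2.57, SE 0.159, adjusted p = 1.4e-12), Eya1 (2.50) and Lmo3 (2.35), all regulators of forebrain or progenitor development. The lipase Pla2g7 (2.50), the sodium pump subunit Fxyd6 (2.45) and Moxd1 (2.64) were higher as well. So was the antisense transcript Pax6os1 (2.90), whose strand is uncertain. Crym, which binds thyroid hormone, was lower in the wedge (-6.88, SE 0.225, adjusted p = 5.4e-19, 10.9 against 1328 CPM), with the ventral and anterior homeobox genes Six3 (-6.83), Vax1 (-6.06) and Nkx6-2 (-4.88). Klf2 (-4.34, SE 0.189, adjusted p = 8.0e-15, 48.5 against 976 CPM), Lmo1 (-3.99), the chloride channel relative Ano3 (-5.17) and the cation channel Trpm3 (-3.74) were lower. With 2 counts each in the wedge, Otx2 was lower 84.4-fold (23.2 to 699 by counting) and Six3os1, an antisense transcript of uncertain strand, 167-fold (46.2 to 1385).

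The dorsal domain list rose in 5 of 8 genes (5 up and 2 down over the list alone, median 1.13, camera adjusted p = 7.4e-11), Emx1 by 3.21 and Pax6 by 1.65. The ventral domain list fell in 6 of 7 (6 over the list alone, median -3.46, camera adjusted p = 1.1e-34). Immediate early genes fell in 12 of 14 cases (14 over the list alone, median -1.62, camera adjusted p = 3.6e-42), Zfp36 by 2.85 and Fos by 0.91. Interferon genes fell in 14 of 17 cases (14 over the list alone, median -0.97, camera adjusted p = 7.0e-24), Rsad2 by 2.44. All 8 MHC class I genes fell (8 over the list alone, median -0.91, camera adjusted p = 3.6e-13). Reactive astrocyte genes fell in 6 of 12 cases (6, median -0.96, camera adjusted p = 2.2e-08), the chemokine Cxcl10 by 2.78. Also falling were ependymal and motile cilium genes (8 of 17, 9 over the list alone, median -1.10, camera adjusted p = 6.2e-09) and cholesterol synthesis (9 of 14, 10, median -0.59, camera adjusted p = 1.6e-07). Neuroblast genes (9 down and 1 up of 13, 11 and 1, median -1.06, camera adjusted p = 8.1e-06) fell as a list, and so did cell cycle genes (2 of 28, 1, median -0.39, camera adjusted p = 0.0362). Within dorsal pallial B cells the medians were 0.054 for neuroblast and 0.051 for cholesterol genes, and within quiescent B cells 0.112 for cell cycle genes. Extracellular matrix genes rose in 5 cases and fell in 2 of 16 (7 and 2 over the list alone, median 0.28, camera adjusted p = 0.0062), Tnc by 1.85. Mitochondrial transcripts had a median of 0.26 with 1 of 13 up (1, camera adjusted p = 0.0051). Ribosomal protein genes had a median of -0.14 with 1 up and 2 down of 91 (2 down over the list alone, camera adjusted p = 0.0477).

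With an estimated correlation these 13 lists had adjusted p = 0.454 to 0.830, and by fry 0.225 to 0.525. Ventricular stem cell genes split evenly (3 up and 3 down of 10, median 0.03), with Prom1 (1.70), Hopx (1.78) and Igfbp5 (1.25) up. Within dorsal pallial B cells Prom1 stood at -0.019 and Hopx at -0.22. No call was made by camera for homeostatic astrocyte (3 up, 2 down of 21), quiescence (3 up, 2 down of 16), activation (3 down of 14), apical junction (3 up, 4 down of 16) or Shh, Wnt and BMP target genes (1 up, 4 down of 11, camera adjusted p = 0.0998). Single genes among them, Gsx2 (-3.13), Sp5 (-3.33) and Lef1 (-4.23), were lower. Oligodendrocyte precursor markers had a median of 0.30 and a mean of -0.22, and endothelial and mural markers a median of -0.54 with an upward camera direction.

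In edgeR 818 genes were higher and 1109 lower in wedge B cells of 14394 tested, 344 and 586 of them by more than 2-fold. DESeq2 called 603, edgeR without the replicate block called 0 (1148 at an unadjusted p under 0.05). Within dorsal pallial B cells 13 passed, and the interferon median was -0.29 and the MHC class I median -0.36. No wedge cell is named B1, so this comparison mixes dissection with the B cell name.

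Among B2 cells alone, Tfap2c (log2 3.40, SE 0.261, adjusted p = 1.4e-05), Dmrta2 (2.40), Zic2 (2.35), Nr2f1 (2.31) and Eya1 (2.02) were higher in wedge B2 cells. The matrix protein Tnr (2.13) and Pla2g7 (2.10, SE 0.116, adjusted p = 1.4e-06, 382 against 88.9 CPM) were higher too. Crym (-6.17, SE 0.163, adjusted p = 1.2e-09, 11.3 against 821 CPM), Six3 (-6.51), Vax1 (-5.39), Klf2 (-3.56), the ammonium transporter Rhcg (-3.73) and Notum, a secreted Wnt antagonist (-3.23), were lower. Six3os1, with 2 counts in the wedge and an uncertain strand, was lower 134-fold (36.7 to 1110 by counting).

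In wedge B2 cells ventricular stem cell genes rose in 5 cases and fell in 1 of 10 (5 and 2 over the list alone, median 0.46, camera adjusted p = 9.4e-06), Hopx by 1.37, Thbs4 by 1.46 and Gfap by 0.75, though within dorsal pallial B2 cells Hopx stood at -0.41 and Gfap at -0.20. Homeostatic astrocyte genes rose in 8 and fell in 1 of 20 (11 and 2, median 0.32, camera adjusted p = 0.00017). Quiescence genes did so in 6 and 2 of 16 (9 and 2, median 0.37, camera adjusted p = 0.00063) and extracellular matrix genes in 6 and 2 of 16 (9 and 2, median 0.37, camera adjusted p = 1.1e-05), Tnc by 1.89. Neuroblast genes fell in 11 and rose in 1 of 13 (12 and 1, median -1.51, camera adjusted p = 1.5e-17), Dcx by 1.75. Activation genes fell in 5 of 14 (6, median -0.49, camera adjusted p = 4.9e-06) and cell cycle genes in 6 of 28 (12, median -0.80, camera adjusted p = 6.5e-07). Dorsal domain genes rose in 4 and fell in 2 of 8 (5 and 2, median 0.93, camera adjusted p = 3.3e-08), Emx1 by 2.92 and Pax6 by 1.36. Ventral domain genes fell in 5 of 7 (7, median -3.68, camera adjusted p = 1.5e-36). Immediate early genes fell in 9 of 14 (13, median -0.95, camera adjusted p = 5.5e-22). So did interferon genes in 9 of 17 (13, median -0.50, camera adjusted p = 4.3e-13) and MHC class I genes in 2 of 8 (7, median -0.43, camera adjusted p = 0.00085). Cholesterol synthesis fell in 6 of 14 (7, median -0.34, camera adjusted p = 0.00063) and ependymal genes in 3 of 15 (3, median -0.37, camera adjusted p = 0.037). Mitochondrial transcripts rose in 4 of 13 (12 over the list alone, median 0.35, camera adjusted p = 9.4e-06) and oligodendrocyte precursor markers in 1 of 3 (1, median 0.43, camera adjusted p = 0.037). Adjusted p with an estimated correlation was 0.588 to 0.603 for these 16 lists and 0.344 to 0.415 by fry. Gsx2 (-3.59) and Lef1 (-4.37) were lower. Reactive astrocyte genes stood at 1 up and 1 down of 12 (median -0.01), and endothelial and mural markers had a median of -0.76 and a mean of 0.03.

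The edgeR calls were 562 higher and 524 lower of 13525, with 225 and 297 past 2-fold. DESeq2 called 347, edgeR without the replicate block 0 (815 at an unadjusted p under 0.05), quiescent cells alone 656 and dorsal pallial cells alone 21. In quiescent B2 cells the medians were 0.17 for cell cycle, 0.14 for neuroblast, 0.089 for homeostatic astrocyte and 0.091 for quiescence genes. In dorsal pallial B2 cells they were 0.036 for neuroblast, 0.136 for cholesterol synthesis, -0.037 for homeostatic astrocyte and 0.031 for ventricular stem cell genes.

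Wedge neuroblasts held more RNA of several dorsal transcription factors. Dmrta2 (log2 2.26, SE 0.11, adjusted p = 2.5e-10, 43.8 against 9.14 CPM), the retinoid-binding Rlbp1 (1.80), the matrix protein Sparcl1 (1.71), Nr2f1 (1.54), Zic2 (1.53) and Pax6 (1.28, SE 0.071, 245 against 101 CPM) were higher in wedge A cells. Foxp4 (-3.60, SE 0.202, adjusted p = 1.4e-09, 1.79 against 22.3 CPM), Zic1 (-2.49), the adhesion gene Flrt1 (-2.49), Zfhx3 (-1.98), the nuclear receptor Esrrg (-1.90) and the synaptic adhesion gene Cntnap4 (-2.01) were lower. So was the interferon-induced Samd9l (-1.77). The Wnt effectors Sp5 (-2.87) and Lef1 (-2.07) were lower too.

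Interferon genes fell in 11 of 17 cases (11 down and 1 up over the list alone, median -0.83, camera adjusted p = 2.2e-32), Bst2 by 1.21. MHC class I genes fell in 7 of 8 (8, median -1.04, camera adjusted p = 3.6e-24), Tap1 by 1.23. Cholesterol synthesis rose in 11 of 14 cases (11, median 0.47, camera adjusted p = 1.6e-18), Hmgcs1 by 0.63. The cell cycle list rose in 10 of 30 (16, median 0.30, camera adjusted p = 6.0e-09). Dorsal domain genes rose in 3 and fell in 1 of 5 (3 and 1, median 0.64, camera adjusted p = 7.5e-11). Ventral domain genes fell in 2 of 7 (3, median -1.23, camera adjusted p = 1.5e-05) and reactive astrocyte genes in 2 of 11 (3, median -0.38, camera adjusted p = 0.0083). No single ribosomal protein gene of 92 or mitochondrial transcript of 13 passed, with medians of 0.07 and 0.10 and camera adjusted p = 0.00064 and 0.022. These 9 lists had adjusted p = 0.845 to 0.887 with an estimated correlation and 0.126 to 0.471 by fry. Immediate early genes stood at 2 up and 1 down of 14 (median 0.09), Fos at 0.32 (adjusted p = 0.0300). Signs differ between median and mean for neuroblast genes (-0.01 and 0.06), neuron markers (0.03 and -0.13) and fatty acid oxidation (0.01 and -0.05). Median and camera direction differ for ventricular stem cell (-0.26) and extracellular matrix genes (-0.25). The 3 measured erythrocyte genes did not pass.

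Of 16439 genes, edgeR called 349 higher and 704 lower in wedge A cells, 39 and 233 by more than 2-fold. DESeq2 called 452 and edgeR without the replicate block 0 (632 at an unadjusted p under 0.05).

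**Figure D3:**
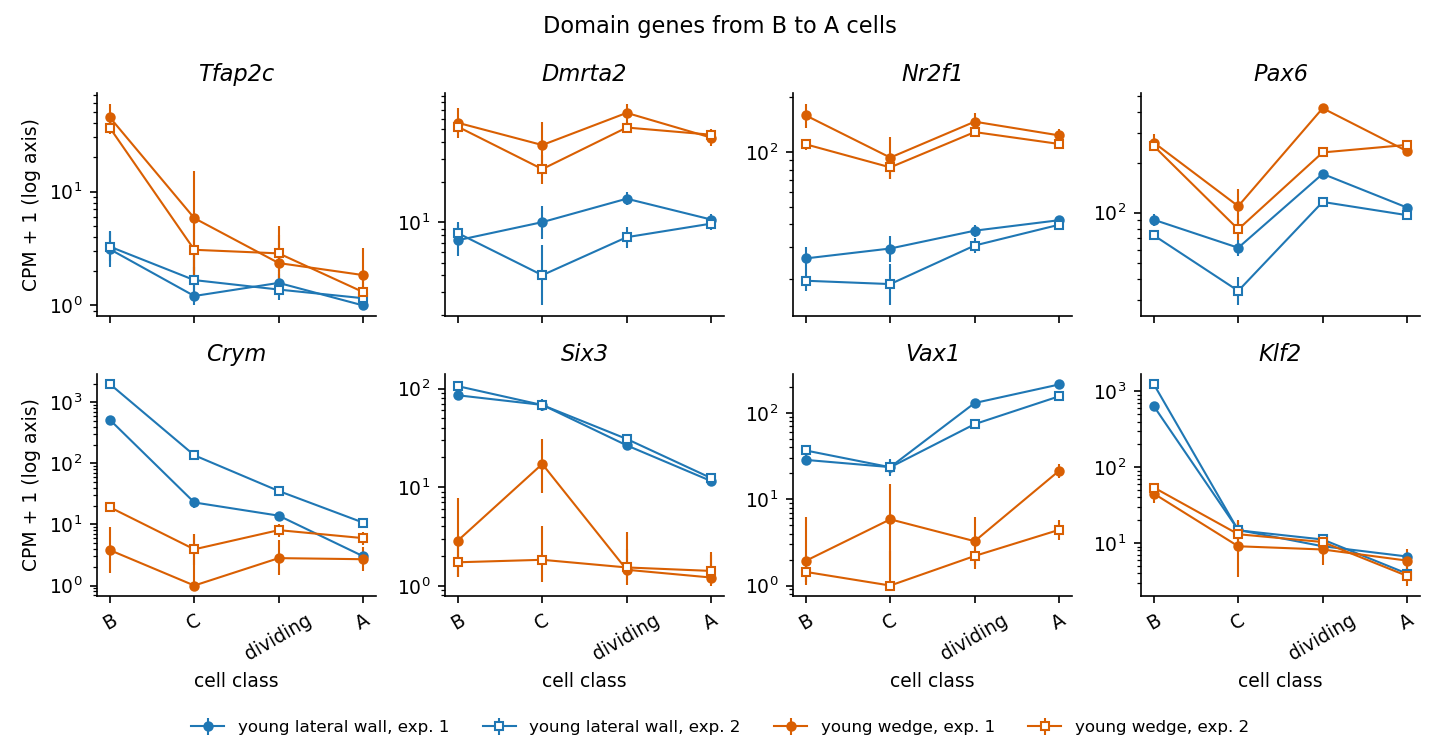
CPM of 8 domain genes in B, C, dividing and A cells of the young lateral wall and wedge in each experiment. Bars are exact 95% Poisson intervals.

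**Figure D4:**
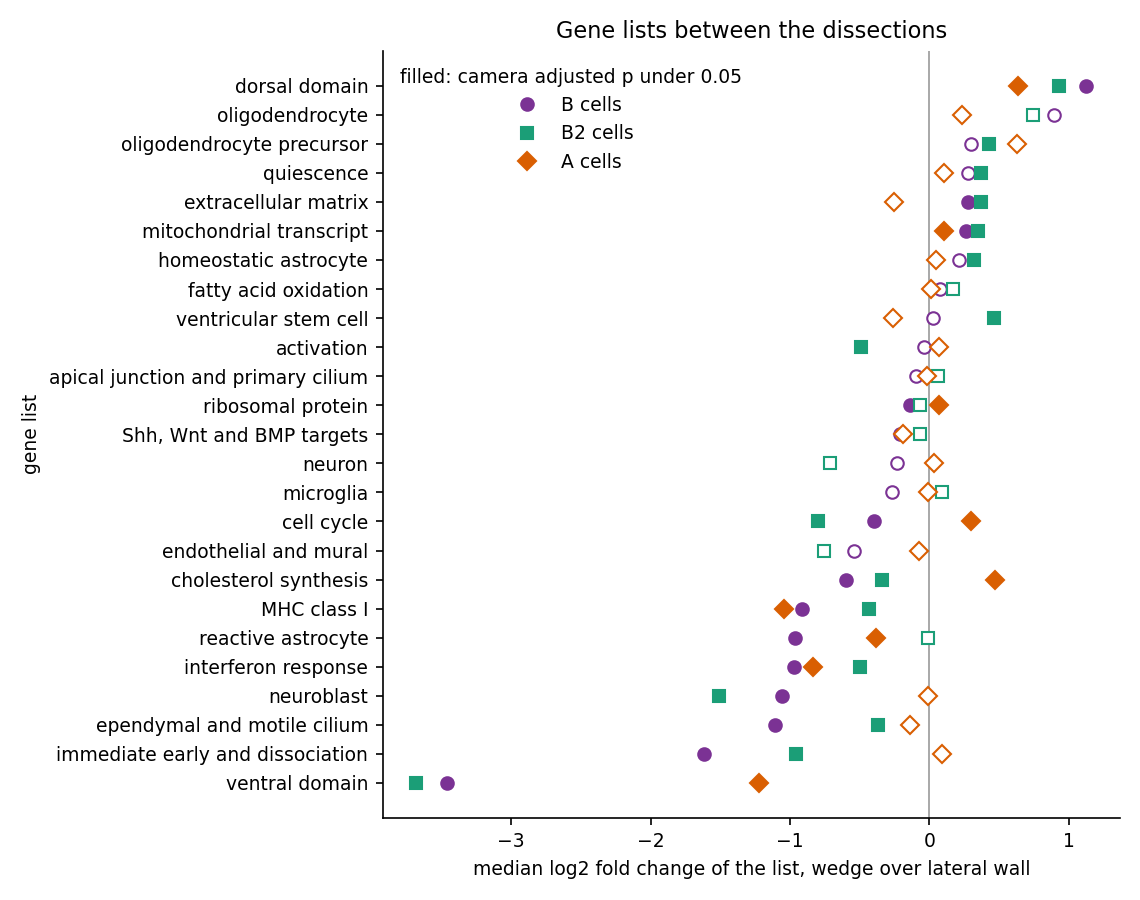
Median log2 fold change of each gene list, wedge over lateral wall, in B, B2 and A cells. Filled points have a camera adjusted p under 0.05.

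Arc, an activity-induced gene, was higher in B2 cells than in parenchymal astrocytes (log2 3.21, SE 0.274, adjusted p = 0.0024, 58.2 against 7.03 CPM). So were the immediate early Egr3 (3.18) and Fos (2.96, adjusted p = 0.0459), the vesicle gene Sv2c (3.26) and Klf2 (3.097). Nes, the stem cell filament (2.51), the Notch ligand Dll1 (2.96) and Tfap2c (3.41) were higher as well. Higher in astrocytes were the GABA-B receptor subunit Gabbr2 (-5.10, SE 0.576, adjusted p = 0.0073, 5.97 against 209 CPM), the potassium channel Kcnma1 (-4.45), the NAD hydrolase Cd38 (-4.32), S100b (-3.93, SE 0.234, adjusted p = 0.0017), the NMDA receptor subunit Grin2c (-3.78) and the matrix linker Hapln1 (-3.67). By pool (lateral wall of experiment 1, lateral wall and wedge of experiment 2) Fos stood at 0.99, 3.72 and 3.98. Cd38 stood at -1.21, -4.49 and -3.88 in the same order.

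Homeostatic astrocyte genes fell in 17 of 22 cases (19 over the list alone, median -1.69, camera adjusted p = 1.3e-28): Agt by 3.27, Gjb6 by 2.86, Aqp4 by 2.09 and the glutamate transporter Slc1a2 by 1.02 (5078 against 9676 CPM). Immediate early genes rose in 12 of 14 (14, median 2.17, camera adjusted p = 4.9e-15) and ribosomal protein genes in 79 of 90 (80, median 1.27, camera adjusted p = 1.1e-55). Activation genes rose in 6 of 13 (8, median 1.36, camera adjusted p = 1.7e-06) and cell cycle genes in 7 of 22 (9, median 0.86, camera adjusted p = 2.8e-05). Rises were also seen for dorsal domain genes in 3 of 6 (3, median 1.33, camera adjusted p = 0.00044) and ventricular stem cell genes in 2 of 10 (2, median 0.76, camera adjusted p = 0.0078). Ependymal genes rose in 3 of 11 (3, median 0.66, camera adjusted p = 0.017) and interferon genes in 1 of 17 (1, median 0.34, camera adjusted p = 0.021). Extracellular matrix genes fell in 7 of 16 (7, median -0.37, camera adjusted p = 0.00025) and fatty acid oxidation in 4 of 12 (5, median -0.38, camera adjusted p = 0.0023). So did mitochondrial transcripts in 2 of 13 (6, median -0.47, camera adjusted p = 0.0015) and microglial markers in 1 of 6 (4, median -1.08, camera adjusted p = 0.0208). Adjusted p for these 13 lists was 0.418 to 0.670 with an estimated correlation and 0.108 to 0.230 by fry. Median mitochondrial shares were 3.52% and 4.87% in astrocytes of the lateral wall and wedge of experiment 2, and 2.44% and 2.90% in B2 cells. Reactive astrocyte genes stood at 3 up of 12 (camera adjusted p = 0.0784). Signs differ for MHC class I genes (median 0.30, camera downward, 2 of 8 down), neuroblast genes (median -0.31, camera upward) and oligodendrocyte precursor markers (median -0.18, mean 0.69).

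With edgeR 869 genes were higher and 1070 lower of 12603, 476 and 603 by more than 2-fold. Leaving out the lateral wall of experiment 1, which leaves only pools of the same mice, gave 3224 calls. Leaving out the lateral wall of experiment 2 gave 60, and leaving out its wedge gave 245. Without the replicate block 0 passed in edgeR (2644 at an unadjusted p under 0.05), against 1538 by DESeq2.

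Lateral wall B cells with any reporter UMI differed from those without in 48 called genes. This grouping is called labelled below, though in experiment 2 it holds 1030 of 1238 B cells, and GFP was in 56.8% of microglia against 60.3% of lateral wall B cells there. GFP there hardly separates labelled cells from background. Labelled cells were also deeper: in experiment 1, 263 held 4700160 UMIs and 128 unlabelled cells 1908167. In experiment 2, 1030 held 9352557 and 208 unlabelled cells 1578883. The thinned fit keeps labels made at full depth, so it does not remove this selection. Nrxn3, a synaptic adhesion gene, was higher (log2 0.86, SE 0.081, adjusted p = 1.6e-20, 714 against 410.3 CPM), and so were the cell cycle inhibitor Cdkn1a (1.10, SE 0.133, adjusted p = 4.6e-13, 108 against 50.7 CPM), Ccl7 (1.54, SE 0.265, adjusted p = 1.2e-05), Tnfaip2 (1.00), the scaffold Akap12 (1.13) and Rbfox1 (0.92). Lower were the chemokine Cxcl2 (-1.08), the lysosomal transporter Abcd4 (-1.06), the linker histone Hist1h1e (-0.71), Heg1 (-0.69) and Cd74 (-0.57). A single unlabelled cell held 55.2% of the Cxcl2 UMIs of unlabelled cells, and a single labelled cell 22.1% of the Rbfox1 UMIs of labelled cells. Rbfox1 stood at 0.184 in experiment 1 and 2.015 in experiment 2. The neuroblast list rose in 4 of 13 genes (9 over the list alone, median 0.69, camera adjusted p = 7.2e-27), Stmn2 by 0.71 and Tubb3 by 0.80. With an estimated correlation its adjusted p was 0.867, and in thinned cells the median was 0.27 with 1 of 10 genes up. Grouped by TdTomato name the direction turned: the list median was -1.56 with 10 genes down, Stmn2 stood at -0.91, Tubb3 at -1.56 and Nrxn3 at -1.58. The reactive astrocyte list rose in 1 of 12 (4, median 0.20, camera adjusted p = 1.5e-05), which was Timp1 (0.79), with opposite signs in the 2 experiments.

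Camera also called 4 lists in which no member passed. Among them were dorsal domain (7 genes, median -0.32, camera adjusted p = 0.0169) and Shh, Wnt and BMP targets (8 genes, 1 down over the list alone, median -0.17, camera adjusted p = 0.0197). The others were cholesterol synthesis (14 genes, median 0.08, camera adjusted p = 0.0402) and ribosomal protein (91 genes, median -0.06, camera adjusted p = 1.5e-05). With an estimated correlation all 6 lists had adjusted p = 0.867, and by fry 0.492 to 0.878. Ependymal genes had a median of 0.21 (16 genes, camera adjusted p = 0.285), interferon genes 0.03 (17 genes) and MHC class I genes 0.01 (8 genes). Signs of median and mean differ for ventricular stem cell (0.02 and -0.05), activation (0.05 and -0.01), ventral domain (-0.03 and 0.03) and oligodendrocyte genes (-0.02 and 0.13).

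The edgeR calls were 39 higher and 9 lower of 12940, or 17 and 7 with DESeq2 size factors, and 13 and 5 passed 2-fold. DESeq2 called 1 gene, edgeR without the replicate block 0 (42 at an unadjusted p under 0.05). It called 2 with thinned cells, 6 with WPRE alone and 0 with GFP alone (823 at an unadjusted p under 0.05).

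Aged cells of the lateral wall held far fewer interferon transcripts than young cells of the same libraries. The summed interferon list stood at a log2 ratio of -2.93 in A cells (-3.07 to -2.79 by counting, 127 aged and 2734 young cells), -2.74 in endothelial cells (-2.83 to -2.65, 69 and 299) and -4.56 in B cells (-4.78 to -4.35, 43 and 391, added later). Each median ranked at 0.0% of random lists. MHC class I stood at -1.08, -0.39 and -3.08 in the same order. In aged A cells Rsad2 stood at 3.62 against 96.7 CPM, Usp18 lower 96.5-fold (33.0 to 468) and Xaf1 24.6-fold (8.39 to 119). In aged B cells Isg15 was at least 94.8-fold lower, Ifit1 101-fold (27.9 to 834), Bst2 stood at 15.4 against 1014 CPM and Cxcl10 at 12.3 against 626 CPM. Slc15a2, a peptide transporter, was higher with age in all 3 classes: 405 against 55.8 CPM in A cells, 279.8 against 38.8 in endothelial cells and 1068 against 109 in B cells.

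Cell cycle genes had a median of 0.29 in aged A cells and 0.82 in aged B cells (percentile 100 in both), but -0.51 in endothelial cells (percentile 1.21, 6 of 28 above 0). Pttg1 stood at 110.4 against 11.8 CPM in A cells, a log2 ratio of 3.23 that was 2.45 in library 1 and 3.75 in library 2. Ventricular stem cell genes had a median of -1.04 in aged B cells (percentile 0.0), reactive astrocyte genes a sum ratio of -1.84 there, and dorsal domain genes -1.32 in aged A cells. By name the aged B cells are 42 B2 cells and 1 B1 cell, the young ones 157 B2 and 234 B1 cells. The B1 name rests in part on TdTomato, and the aged mice were not injected (0 of 43 named TdTomato+). These counts therefore do not measure a change of make-up, though the B cell values may also carry one. Immediate early genes had a median of -0.61 in A cells (percentile 0.0) and 0.53 in endothelial cells (percentile 99.99). Aged endothelial cells had more Fmo2 (334 against 7.597 CPM, log2 5.44, with 5.98 in library 1 and 4.52 in library 2), Mgll (343 against 44.6 CPM) and Cd59a (638 against 117 CPM). There Lcn2 was 141-fold lower (48.2 to 684), Ackr1 at least 16.5-fold, the angiogenic ligand Apln at least 7.38-fold and the haemoglobin gene Hba-a2 at least 192-fold. The 4 erythrocyte genes, all of haemoglobin, were together far less changed, with a log2 ratio of sums of -0.61 (-0.67 to -0.54 by counting, 1 of 4 above 0). Microglial markers had a median of 1.05 (9 of 9 above 0, percentile 99.98) and mitochondrial transcripts 0.61 (13 of 13, percentile 99.97) in aged endothelial cells, whose median depth was 7597 against 15702 UMIs. RNA of other cells and lower quality were not separated from age there. Xist, transcribed in females, stood at 4.22 against 404 CPM in A cells. Age, injection, genotype and sex mix change together between these 2 groups of 1 pool each, so no test was made and all intervals hold counting error only.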

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

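Tests chosen only after the result was seen are those of free ependymal RNA, of abundant ependymal genes, of dorsal pallial B2 cells, of virus exposure, both tests of WPRE and the splits of the astrocyte comparison. For the others the bounds were written down beforehand. The fits without TdTomato+ NN cells and in dorsal pallial B cells, on which some of them rest, were still added after the data were seen.

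A difference between groups marked the wedge effect in B and in A cells, which a joint model of 15789 genes tested directly. Of these, 1045 genes differed in their wedge effect between B and A cells (486 higher and 559 lower in B cells), and 768 had opposite signs. Immediate early genes had wedge medians of -1.61 in B and 0.09 in A cells (difference -1.90, 12 of 14 genes lower, camera adjusted p = 3.7e-44), and cholesterol synthesis -0.59 and 0.47 (difference -1.02, 12 of 14, camera adjusted p = 3.4e-32). Cell cycle genes stood at -0.47 and 0.30 (difference -0.82, 5 of 30, camera adjusted p = 6.9e-08), ribosomal protein genes at -0.15 and 0.07 (difference -0.21, camera adjusted p = 4.7e-07) and activation genes at -0.06 and 0.07 (difference -0.25, camera adjusted p = 0.0233). With an estimated correlation adjusted p was 0.213 for the first 3 lists, 0.940 for ribosomal protein and 0.422 for activation genes. Camera also called lists whose medians had the same sign in both classes. These were neuroblast (difference -1.055, camera adjusted p = 1.15e-09), ependymal (-0.922, 0.000201), ventral domain (-2.023, 0.00305) and reactive astrocyte genes (-0.249, 0.00694). Their adjusted p with an estimated correlation was 0.303 to 0.536. Interferon (adjusted p = 0.707) and MHC class I genes (adjusted p = 0.955) were not called in camera. Wedge B cells hold no cell named B1. Within dorsal pallial B cells the cholesterol median was 0.051 and the cell cycle median -0.126, and within quiescent B cells they were -0.788 and 0.112, so the opposite sign of each list held under 1 of these settings and not under the other.

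Cilium genes were higher in B1 than in B2 cells, and ependymal RNA is the technical candidate. Free ependymal RNA in every droplet is ruled out as the whole cause, since microglia held at most 0.13 of the gain in marker UMIs from B2 to B1 cells. Counting TdTomato+ NN cells as B1 is ruled out as the whole cause as well, because the list median without them was 1.33 times that with them. The dropped cells were not returned to B2 cells, so an effect of the naming on the B2 side was not tested. For ependymal RNA carried by the B1 droplets themselves, the implied share varied between genes 9.76-fold and 7.52-fold from lower to upper quartile. Both ratios pass the bound of 4 set beforehand, which speaks against an even share of ependymal RNA. Resampling of genes, which was no part of that rule, reached down to 3.94 in experiment 2. The implied share was above 0 for 85.4% and 82.6% of genes, so a part played by such RNA cannot be told. Of 48 abundant ependymal genes, 3 (Ccdc153, Ecrg4 and Tmem212) lay far below the level that the median implied share of 2.81% and 2.03% needs in both experiments, which speaks against whole ependymal cells, but that share of 0.0625 (0.0131 to 0.172) is under the 0.1 asked for.

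Interferon and MHC class I genes were lower in the wedge. Lower depth of wedge B cells is ruled out as the whole cause, with a thinned median 0.77 times the full one, just past the bound. Within dorsal pallial B cells the interferon median was 0.29 times that of all B cells. That setting also drops nearly all B1 cells. In B2 cells alone the ratio was 0.643 (0.423 to 1.05) for interferon and 0.995 (0.392 to 1.65) for MHC class I genes. For B cells, domain make-up therefore cannot be told from the loss of B1 cells. Neither can act in microglia or oligodendrocyte precursors, whose interferon medians were -0.378 and -0.53, and -0.48 and -0.621, in the 2 experiments. Greater exposure of the lateral wall to virus cannot be told: 20 of 21 pairs of class and experiment lay under 0, from -1.22 in C cells, and the highest was 0.032 in myeloid cells of experiment 2. Aged uninjected cells also held less interferon RNA, but age changes with injection there, so an uninjected young wedge and lateral wall would be the test.

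WPRE was found in classes far from the ventricle, such as microglia and neuroblasts. Free WPRE RNA is ruled out as the main source, because thinned aged cells of the same libraries held it in 3 of 321 cases against 420 of 4582 young cells, an upper bound of 0.295 times the young share. Low transcription from the Ai14 locus without recombination could explain WPRE in these classes. The wedge held at least 0.632 times the lateral wall share in microglia and A cells, and aged cells without the locus held little. The labels say that wedge cells were checked by microscope for label, which counts of WPRE do not measure.

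In B2 cells against astrocytes, 10 splits of the 6 sums are too few to judge by, with 1 split at the real value of 1939 and 0 as the highest other. By the Dixon test 0 of 54 groups held a library of experiment 2 apart from its other 3, where chance gives about 2.7, and the 2 libraries of experiment 1 cannot be tested this way.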

How the results depend on the processing

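Alternatives chosen only after results were seen are fits in 1 domain, in quiescent cells, without TdTomato+ NN cells, by TdTomato name and with reporters kept in the sums, and the aged values in B cells. The limits lie in 2 experiments, 1 residual degree of freedom in most fits and small sums, of as few as 42 cells in the 6 comparisons and fewer in fits of 1 domain, such as 20 dorsal pallial B2 cells of the lateral wall in experiment 1. Depth per cell in experiment 2 (median 8033 UMIs) is below that of experiment 1 (15809). Of 2402 values of named genes under alternatives, 1847 were labelled the same, 475 lost the call, 54 moved and 26 reversed. The same label means no lost, gained or reversed call. With a pool left out of 4 sums it means a value within 1 SD of the pair values from the main one. Some settings, such as at least 30 cells per sum, repeat the main fit, so this count overstates how stable the values are. Of 865 list medians 678 stayed, 167 moved and 20 reversed, and of 240 aged gene values 206 stayed and 34 moved. Within 1.5 times of the main count were, for B1 against B2 cells, 1272 with DESeq2 size factors, 1881 without a filter, 1086 without TdTomato+ NN cells, 1325 in quiescent cells and 1459 with reporters kept. Where a pool is left out of 4 sums, no test was possible, and the shallower thinned cells were dropped. Except where a setting is built from fewer cells or sums, the cause was not tested.

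The fit by 10x library treats libraries of the same mice as replicates, and its spread is technical only. Counts of calls by DESeq2 were 397 for B1 against B2 cells, 603, 347 and 452 for the wedge in B, B2 and A cells, and 1 for labelled B cells. With the replicate block by 10x library they were 2500, 3779, 2355 and 1944, 4816 for B2 cells against astrocytes and 1 for labelled cells. Without the replicate block edgeR called 0 in each of the 6 (557, 1148, 815, 632, 2644 and 42 at an unadjusted p under 0.05), and all 169 called named genes lost their call. The pairing is part of the design, and no crossed pairing was tried. No paired analysis was made for class and reporter shares, for which no test was planned. No paired analysis was possible for aged cells because they form 1 pool.

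In experiment 1 alone by library the counts were 941 for B1 against B2 cells, 786, 404 and 489 for the wedge in B, B2 and A cells, 1127 for astrocytes and 15 for labelled cells. In experiment 2 alone they were 2555, 4496, 2879, 2054, 5181 and 11. Leaving out a pool moved B2 cells against astrocytes between 60 and 3224 (245 without the wedge of experiment 2). Thinned cells gave 731 calls for B1 against B2 cells and 2 for labelled cells. Cells without ependymal marker UMIs gave 159, ventral subpallial cells 217, with or without TdTomato+ NN cells, and dorsal subpallial cells 0 (1003 at an unadjusted p under 0.05 in edgeR). In the wedge, dorsal pallial cells gave 13 for B and 21 for B2 cells, and quiescent B2 cells 656. Labelled cells gave 24 with DESeq2 size factors, 28 at 2 or more reporter UMIs, 6 with WPRE only, 0 with GFP only (823 at an unadjusted p under 0.05 in edgeR) and 1086 by TdTomato name, a grouping that repeats B1 against B2 cells without TdTomato+ NN cells.

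List tests called 11, 13, 16, 9, 13 and 6 lists in the order of the 6 comparisons. With an estimated correlation camera called 0 in each, and fry called 1 for B1 against B2 cells (neuron markers) and 0 in the other 5.

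For B1 against B2 cells, signs reversed for Prom1 in ventral subpallial cells (0.61) and for Dlx6os1 (0.45), Adarb2 (0.37), Nav3 (0.78) and Vcam1 (-0.006) in dorsal subpallial cells. In quiescent cells Dlx6os1 stood at 0.015, Synpr at 0.45 and Dcx at 0.12. The cell cycle median was 0.05 in ventral subpallial cells, 0.20 there without TdTomato+ NN cells, 0.36 in dorsal subpallial cells and 0.079 in quiescent cells. The neuroblast median was 0.51 in dorsal subpallial and 0.07 in quiescent cells, and the neuron median 0.05 in quiescent cells. By construction the quiescent setting drops the activated cells, which are more frequent among lateral wall B2 cells.

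In wedge against lateral wall B cells, dorsal pallial cells gave Hopx at -0.22, Prom1 at -0.019, a neuroblast median of 0.054 and a cholesterol median of 0.051, and quiescent cells a cell cycle median of 0.11. In B2 cells, dorsal pallial cells gave Hopx at -0.41, Gfap at -0.20, and medians of -0.037 for homeostatic astrocyte, 0.036 for neuroblast and 0.14 for cholesterol genes. Quiescent B2 cells gave 0.17 for cell cycle and 0.14 for neuroblast genes. The ependymal median of B2 cells against astrocytes was -0.13 in experiment 1 alone.

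In labelled cells Timp1 stood at -0.051 in experiment 1 alone by library and between -0.072 and 1.19 with a pool left out, and Cd74 at 0.38 with GFP only. By TdTomato name, Dlx6os1 stood at -2.66, Csmd3 at -0.013, Lrrtm4 at -0.40, Rbfox1 at -1.74, Nav3 at -2.01, Nrxn3 at -1.58, Stmn2 at -0.91 and Tubb3 at -1.56. In the same grouping Cxcl2 stood at 0.38, Abcd4 at 0.053 and Cd74 at 1.06, with medians of -1.56 for neuroblast and 0.13 for ribosomal protein genes. In experiment 2 alone the cholesterol median was -0.025 and the ribosomal protein median 0.061.

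WPRE shares at 2 or more UMIs were 82.6% and 82.3% in lateral wall ependymal cells, 35.0% and 34.9% in lateral wall B cells, 18.6% and 22.0% in wedge B cells and 7.53% and 8.11% in microglia. In thinned cells they were 69.2% and 76.9%, 23.8% and 36.8%, 20.9% and 31.2%, and 9.59% and 11.9%. B1 shares stayed within their intervals in every library. The aged interferon ratio was -3.17 and -2.74 in A cells and -2.91 and -2.53 in endothelial cells in library 1 and library 2 alone, and in B cells it stayed within its interval.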

Other observations

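Along the lineage from B through C to A cells, domain genes followed separate courses. Tfap2c fell away in the wedge from 43.9 and 35.4 CPM in B cells to 4.85 and 2.08 in C cells and 0.849 and 0.311 in A cells, while Dmrta2 stood at 55.1 and 51.4, 37.2 and 24.2, and 42.4 and 44.7 CPM. In the lateral wall Vax1 stood at 27.5 and 35.7 CPM in B cells and 212.5 and 155 in A cells, Zic1 at 5.45 and 4.03 against 21.7 and 18.6, Six3 at 84.4 and 105 against 10.5 and 11.4, and Klf2 at 637 and 1239 against 5.66 and 2.97. These are sums per class with counting error only, and no test was made along the lineage.

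Of 13798 genes tested in both B and A cells, 751 and 332 were higher in the wedge, 87 in both, where independent calls give 18.1. Lower in the wedge were 1037 and 644, 228 in both (48.4 if independent), and 84 genes were called in opposite directions. The cells differ but the pools are shared, so some overlap arises without a common effect of the wedge.

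In aged B cells the protamine gene Prm1 stood at 1981 CPM against 0.908 in young B cells (log2 10.98, with 11.36 in library 1 and 10.19 in library 2), and Pde10a at 1996 against 88.8. The aged mice carry the hGFAP:GFP transgene and the young do not, so for both genes age cannot be told from genotype. Gt(ROSA)26Sor, the transcript of the locus that carries the reporter in the young mice, stood at 43.4 against 8.42 CPM in aged A cells, a log2 ratio of 2.37 that was 2.21 in library 1 and 3.37 in library 2. Of the aged cells, 24 of 43 B cells held GFP, the transgene of these mice, and 2 of 43 held WPRE. Only 1 of 43 aged B cells was named B1, a name that rests in part on TdTomato and so on injection, which these mice did not receive.

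The 2 lanes that belong to no sample held 12889 and 11372 cells and 144110611 and 149879685 UMIs, with 0 counts of Cre, GFP and WPRE. Aged cells held GFP at 44.8 CPM and WPRE at 1.88 CPM.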
